A study of Mus musculus with 6 samples.

How the data were processed

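Messenger RNA from thioglycollate-elicited peritoneal macrophages of WT and Tg-ACE mice had been isolated with a spin-column kit, made into stranded poly-A libraries and sequenced as single 75-base reads on an Illumina NextSeq instrument to an average of about 20 M reads, per the labels. The authors deposited 1 table of RSEM expected counts per gene for the 6 samples, with no normalization. STAR 2.5.0 and RSEM 1.2.25 and the builds mm10 and GRCh38 are named in the submitters' processing notes, which do not give the role of each. The strand setting of the counting is not given in the sources used here. Between 11.0% and 11.4% of the values in a library were not whole numbers, and all values were rounded to whole counts before use. Expected counts divide a read that matches several transcripts between them, so genes with near-identical copies carry an extra error.

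The table held 25509 gene rows and 92 rows of ERCC spike-in sequences. The spike-in rows summed to 1 count over all libraries and were left out of library sizes and tests. It held 0 columns of samples that are not in the labels. A symbol stood on more than 1 row for 69 gene rows, and such rows were kept apart by their gene identifiers, so that a list can hold more tested rows than symbols. Positions, strands and gene types came from the GENCODE vM21 annotation of GRCm38, in which 25251 identifiers were found. Library totals ranged from 24294258 to 28120394 expected counts, and 3 counts, the smallest level treated as detected, correspond to between 0.107 and 0.123 CPM. Such depth-based limits cover counting error only. No pair of libraries was identical. The mean chi-square per gene was at least 12.8 for every pair, far beyond sampling noise, so each library counted as 1 sample.

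Groups came from the sample titles (WT and Tg-ACE). The series' design text names the second group Tg-NKO where its title and the sample labels say Tg-ACE, and the sample labels were followed. Descriptions give the experiment code Exp-156 for replicate 1 of each group and Exp-156b for replicates 2 and 3.

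Tg-ACE was compared with WT in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, TMM normalization and the filterByExpr filter, which kept 12827 genes, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are Tg-ACE minus WT. CPM values use TMM-scaled library sizes, and log2 CPM values use a prior count of 2. The standard error is the log2 fold change divided by the square root of its F statistic. Ace, Dhrs7 and Gm10709 were also compared by an exact two-sided permutation test of log2 CPM over all 20 assignments. The replicate numbers were checked as pairs through the correlation over genes of the deviations from group means. Same-numbered libraries gave 0.856, 0.483 and 0.637, all above 0.1, so the numbers were at first taken to pair the samples. Crossed pairs of replicates 2 and 3 gave 0.615 and 0.539. With the experiment code removed the pairs numbered 2 and 3 gave -0.178 and -0.101 and the crossed pairs -0.0939 and -0.143. The pairing seen therefore goes with the experiment codes, and replicates 2 and 3 were not shown to be pairs by number. The fit with the replicate block is still given beside the results it changes, but it divides Exp-156b by replicate number only.

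In all, 39 gene lists, written down before the data were examined together with the named-gene rule, the design and most alternatives, covered pathways (nuclear and mitochondrially encoded oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, PPAR targets, cholesterol and lipid synthesis, cholesterol efflux, scavenger receptors, glycolysis and hypoxia, NADPH oxidase and antimicrobial effectors, glutathione and NRF2 targets, pro-inflammatory and alternative activation, type I interferon response, MHC class I and II presentation, lysosome, phagocytosis, complement, renin-angiotensin system and peptidases, chemokines, unfolded protein response, cell cycle), RNA quality and background (immediate early and heat shock genes, ribosomal proteins, histones, sex-linked genes, C57BL/6 substrain genes) and cell types (large peritoneal macrophages, monocytes and small peritoneal macrophages, macrophage core genes, neutrophils, eosinophils, mast cells and basophils, B cells, T and NK cells, dendritic cells, mesothelial cells and fibroblasts, erythroid cells and platelets). The 37 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Irg1 was matched to its newer symbol Acod1 through its identifier, and Clec7a, Mx2, 5 immunoglobulin genes and 3 T cell receptor genes of these lists were not analysed here.

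The rule for named genes took Ace, then up to 12 genes per direction with the largest change among genes that passed, did not overlap between groups and reached 5 CPM in the higher group, leaving out unnamed gene models, and the 5 with the smallest p per direction where fewer than 5 passed. From each list it took up to 4 members with the smallest p and at least 5 CPM for lists described in detail and up to 2 for others. A few genes that these rules or tests would name are not reported here.

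Alternatives were relative log expression factors, library totals and upper-quartile factors in place of TMM, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust edgeR, no filter, a filter of 5 CPM in at least 3 samples, a log2 fold change of at least 1, the replicate block, the experiment code as a term, the Exp-156b libraries alone, each library left out in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were DESeq2, limma-voom and robust edgeR with the experiment code, an offset for transcript length and GC content (alone, with the code and with the block), the length and GC offset fitted without the genes of the list tested, an estimated correlation with the code, with the block and in Exp-156b alone, the lists in Exp-156b alone, and leaving out each library with the code as a term. Copies of Gm10709 were sought with blastn among the vM21 transcripts at 95% identity or more over at least 300 bases.

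The fits were tested on simulated data with 200 changed genes drawn from the real means and library sizes. With no experiment difference and the spread of the genotype fit, 0% of 1.5-fold, 17.1% of 2-fold and 75% of 4-fold changes were found, with 10 false calls among 12656 genes. With the experiment difference kept, the genotype fit found 0%, 30% and 66.7% with 0 false calls among 12685 genes, and the fit with the experiment code 67.1%, 72.9% and 98.3% with 20 false calls. The 10 false calls stood beside 0, 12 and 45 true ones, and the 20 beside 47, 51 and 59. Both are a larger share of calls than an adjusted p threshold of 0.05 is meant to allow. A simulation with no changed gene, fitted only with the experiment code, gave 0 calls. In a simulated list test over 12680 genes a list of 30 genes changed 1.3-fold was recovered, and 3 of 200 unchanged lists had p under 0.05. Genes were drawn independently there and the lists at random, so it does not test the preset correlation where members of a list move together.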

Results

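Poly-A RNA was sequenced from peritoneal macrophages of C57BL/6 mice to ask how gene expression differs when angiotensin-converting enzyme (ACE) is overexpressed. ACE is the peptidase that makes angiotensin II from angiotensin I. The 6 libraries formed 2 groups of 3, wild-type (WT) and Tg-ACE, the ACE-overexpressing mice. The cells had been elicited with thioglycollate, an irritant that draws macrophages into the peritoneal cavity, and were collected on day 4, purified on a Percoll density gradient and kept after 2 h of adherence. The WT libraries held 24294258, 28010104 and 24715977 expected counts and the Tg-ACE libraries 28120394, 25869202 and 24678268, with between 15577 and 15899 genes counted at least once per library. Replicate 1 of each group carries the experiment code Exp-156 and replicates 2 and 3 carry Exp-156b, and the labels do not say what the codes stand for. Nothing in the labels says that the replicates came from separate mice, so the p-values measure the spread between these samples, which may be technical between replicates 2 and 3. Replicate 1 of each group differed from them in sex markers and so came from other mice.

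Ace mRNA was higher in each Tg-ACE library than in any WT library, at 52.7 ± 41.6 counts-per-million (CPM; SD, n = 3) against 12 ± 4.58 (SD, n = 3). The WT replicates stood at 16.7, 7.60 and 11.6 CPM and the Tg-ACE replicates at 100.6, 25.6 and 31.8 CPM, from 409, 214, 291, 2862, 643 and 774 counts. Within Exp-156 the Tg-ACE library held 6.01 times the Ace CPM of the WT library, and within Exp-156b the mean of 2 Tg-ACE libraries was 3.00 times that of 2 WT libraries. The gene (ENSMUSG00000020681.14) lies on chromosome 11 at 105967945 to 105989964 on the forward strand of GRCm38. Its log2 fold change was 2.14 (SE 0.60), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (unadjusted p = 0.0117, adjusted p = 1), and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. With the experiment code in the edgeR fit the log2 fold change was 1.95 (adjusted p = 0.136), and without Tg-ACE replicate 1 it was 1.26 in the genotype fit. Keeping the code and leaving out WT replicate 3 gave 2.24 (edgeR adjusted p = 0.0154), and DESeq2 with the code called Ace (log2 fold change 1.93, adjusted p = 3.9e-05), both settings chosen after the result was seen.

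The genes that set the genotypes apart most clearly were Dhrs7 and Gm10709, both lower in all 3 Tg-ACE libraries. Dhrs7, which encodes a short-chain dehydrogenase/reductase, stood at 48.2 ± 2.54 CPM in Tg-ACE and 96.3 ± 1.56 in WT (SD, n = 3), a log2 fold change of -1.0. Gm10709, a processed pseudogene of the ribosomal protein gene Rpl29, stood at 2.73 ± 0.876 CPM against 32.8 ± 2.27 (SD, n = 3), a log2 fold change of -3.59. Rpl29 itself stood at 272.9 ± 27.7 CPM in Tg-ACE and 178.5 ± 3.27 in WT (SD, n = 3), a log2 fold change of 0.61. Because Gm10709 is 99.2% identical to Rpl29 over 480 bases, reads can be divided between them, and both values are uncertain. Dhrs7 lies on chromosome 12 at 72650353 to 72664909 (reverse strand), Gm10709 on chromosome 9 at 7751725 to 7752204 and Rpl29 on chromosome 9 at 106429454 to 106431568 (both forward strand).

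Across 12827 tested genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in the fit on genotype alone. The smallest adjusted p was 0.0708 for Gm10709, and Dhrs7 had 0.0750. At an unadjusted p under 0.05 there were 126 genes, 58 higher and 68 lower in Tg-ACE, where chance alone would give 641 among exchangeable libraries. These libraries are not exchangeable, because each group holds both experiment codes, which widens the spread. Other groupings of them with 1 Exp-156 library per side gave 51 to 59, or 153 where only the genotype labels within Exp-156 were exchanged. The exchanged labels thus gave more genes than the true ones, and 46.4% of tested genes had the same direction in both experiments. On the same genes DESeq2 called 9 (3 higher, 6 lower) and limma-voom 1, Gm10709. With the experiment code in the edgeR fit, Gm10709 (adjusted p = 0.00102) and Dhrs7 (adjusted p = 0.00177) fell in Tg-ACE and no gene rose, with 831 genes at an unadjusted p under 0.05. The replicate number as a block called the same 2 genes (adjusted p = 0.00158 and 0.0142 in edgeR), as did the 4 libraries of Exp-156b alone (adjusted p = 0.0243 and 0.0256). The log2 fold change of Dhrs7 was -0.94 within Exp-156 and -1.03 within Exp-156b, and that of Gm10709 was -4.01 and -3.39. The groups did not overlap for 305 genes higher and 325 lower in Tg-ACE, 4.91% of those tested. Chance gives 10% for exchangeable libraries, which these are not, as the experiment codes make the groups overlap.

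**Figure D1:**
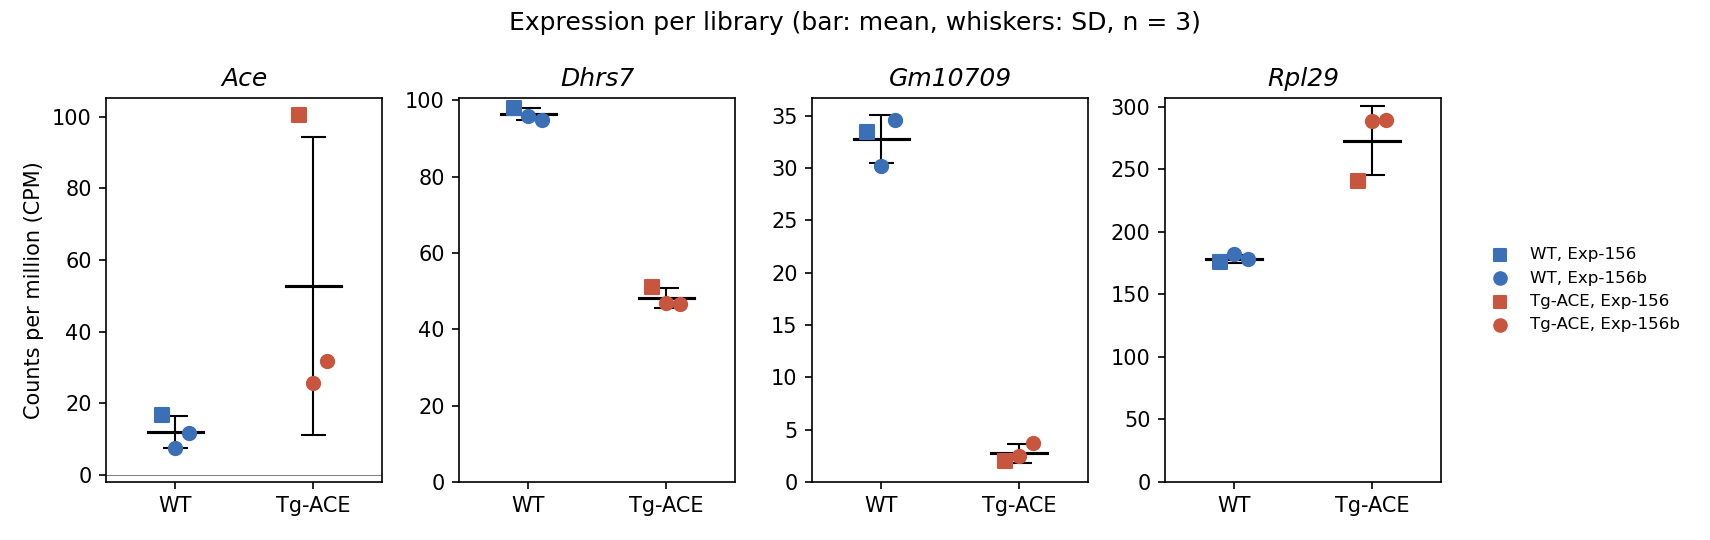
Expression of Ace, Dhrs7, Gm10709 and Rpl29 in CPM for each library, with squares for Exp-156, circles for Exp-156b, bars for group means and whiskers for the SD (n = 3). Dhrs7 has a mean of 96.3 in WT and 48.2 in Tg-ACE, and Ace reaches 100.6 in Tg-ACE replicate 1.

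No named gene passed in the genotype fit, and the 5 with the smallest p in each direction, among genes whose groups did not overlap, are given with their values (CPM as mean ± SD, n = 3). Besides Rpl29, the higher ones were Man2a2, a Golgi mannosidase of N-glycan processing (166.1 ± 6.97 against 120.2 ± 8.75 CPM, log2 fold change 0.47), Atp10a, a phospholipid flippase (0.64), the semaphorin gene Sema4b (0.57) and the aldo-keto reductase gene Akr1b8 (0.37). Besides Dhrs7, the lower ones were Nudt16, a nucleotide hydrolase gene (21.5 ± 3.79 against 38.2 ± 2.0 CPM, log2 fold change -0.83), the transporter gene Slc38a6 (-0.55), Hddc3 (-0.73) and Uimc1, which acts in DNA damage signalling (-0.37). Sema4b, Hddc3 and Man2a2 lie together on chromosome 7 (80.2 to 80.4 Mb), and Dhrs7 and Slc38a6 on chromosome 12 (72.7 to 73.4 Mb). Nudt16 and Rpl29 lie near each other on chromosome 9 (from 105.1 and 106.4 Mb). Neighbours like these need not be separate differences, and whether their closeness has a cause other than ACE was not tested place by place. DESeq2 called Rpl29, Man2a2, Nudt16 and Slc38a6 along with Dhrs7 and Gm10709. Its other 3 genes, chosen after their values were seen like Gm10709, were the zinc finger gene Zfp30 (1.07 ± 0.252 against 3.96 ± 0.665 CPM, log2 fold change -1.89), the pseudogene Gm1840 (-1.49) and 1810049J17Rik (1.91).

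The libraries separated by experiment code before genotype. The first principal component held 74.6% of the variance and placed the 2 Exp-156 libraries at -63.7 and -55.8 and the 4 Exp-156b libraries between 26.2 and 34.2. The second held 7.63%, with WT replicate 2 at 20.7 and Tg-ACE replicate 2 at -25.6. Markers of sex followed the code and not the genotype. Xist, the RNA that silences an X chromosome in females, stood at 0.41 and 0.53 CPM in Exp-156 and between 327.3 and 454.5 CPM in Exp-156b, while the Y-linked Ddx3y stood at 48.0 and 51.6 CPM in Exp-156 and at or below 0.11 CPM in Exp-156b. The biological coefficient of variation was 0.310 in the genotype fit and 0.108 with the code as a term.

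**Figure D2:**
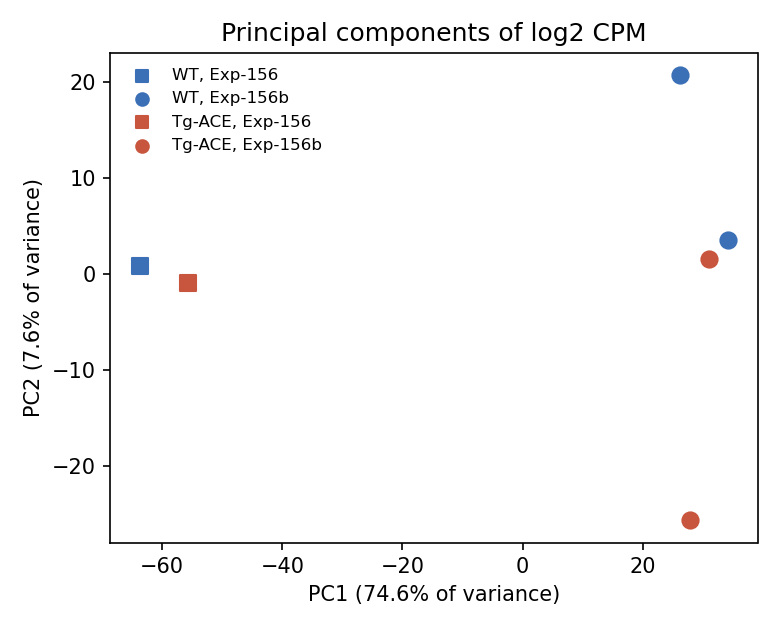
First and second principal components of log2 CPM for the 6 libraries, coloured by group and shaped by experiment code, with the percent of variance on each axis. The Exp-156 libraries lie at -63.7 and -55.8 on the first axis and the Exp-156b libraries between 26.2 and 34.2.

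Nuclear-encoded oxidative phosphorylation, fatty acid oxidation and PPAR target genes were slightly higher as groups in Tg-ACE by camera with its preset correlation (adjusted p = 0.956, 0.956 and 0.880 with an estimated correlation). The tricarboxylic acid cycle and mitochondrially encoded oxidative phosphorylation lists did not pass (camera adjusted p = 0.359 and 0.592). Of the 62 nuclear-encoded oxidative phosphorylation genes, 60 lay above 0 and 2 below, with a median log2 fold change of 0.08 (camera adjusted p = 3.4e-07; adjusted p = 0.956 with an estimated correlation). Members included the ATP synthase subunit genes Atp5d (115.8 ± 7.64 against 100.2 ± 5.23 CPM, log2 fold change 0.21), Atp5k (0.26) and Atp5g2 (0.40) and cytochrome c, Cycs (0.23). The list's median was -0.09 within Exp-156 and 0.15 within Exp-156b. The cytosolic ribosomal protein list, a list of RNA quality that did not pass over all 6 libraries, moved alike, with -0.10 and 0.12 within the experiments. It passed in Exp-156b alone (camera adjusted p = 1.4e-04; adjusted p = 0.947 with an estimated correlation). Fatty acid oxidation genes had 22 of 25 above 0, with a median of 0.08 (camera adjusted p = 0.00132; adjusted p = 0.956 with an estimated correlation) and 0.05 and 0.11 within the experiments. They included the mitochondrial carnitine carrier Slc25a20 (29.9 ± 4.87 against 24 ± 3.19 CPM, 0.32), the acyl-CoA dehydrogenases Acadvl (0.16) and Acadl (0.13), and carnitine acetyltransferase, Crat (0.19). PPAR target genes, which answer to fatty-acid-sensing nuclear receptors, had 14 of 19 above 0, with a median of 0.16 (camera adjusted p = 0.00668; adjusted p = 0.880 with an estimated correlation) and 0.15 and 0.12 within the experiments. The receptor gene Pparg stood at 86.7 ± 7.32 CPM against 75.4 ± 5.01 (0.20) and the fatty acid transporter Cd36 at 1869 ± 311.2 against 1625 ± 183.1 CPM (0.20), though Cd36 was 0.59 within Exp-156 and -0.00 within Exp-156b. The oxidative phosphorylation call ended without Tg-ACE replicate 3 (median 0.02), and its median was 0.19 without Tg-ACE replicate 1 and 0.05 without Tg-ACE replicate 2. The fatty acid and PPAR calls ended without Tg-ACE replicate 1 (medians 0.06 and 0.02), and the medians were 0.15 without WT replicate 1 for fatty acid oxidation and 0.07 without WT replicate 2 for PPAR targets.

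Type I interferon response genes were also higher as a group, with 25 of 28 above 0 and a median log2 fold change of 0.21 (camera adjusted p = 8.4e-06; adjusted p = 0.956 with an estimated correlation). The antiviral genes Oas1a (74.5 ± 2.39 against 60.4 ± 5.45 CPM, log2 fold change 0.30), Ifit3 (0.79), Oasl1 (0.29) and Rtp4 (0.66) were the members with the smallest p. The list's median was 0.46 within Exp-156 and 0.00 within Exp-156b, its call ended without Tg-ACE replicate 1 (-0.04, adjusted p = 0.664 in camera), and it was 0.11 without WT replicate 3. Lysosome genes had 29 of 34 above 0, with a median of 0.10 (camera adjusted p = 0.00105; adjusted p = 0.956 with an estimated correlation) and 0.05 and 0.13 within the experiments. They included the lysosomal proteases Lgmn (2092 ± 93.8 against 1752 ± 144.7 CPM, 0.26) and Ctsl (0.31) and the proton pump subunit Atp6v1b2 (0.12). The lysosome call ended without WT replicate 1 (0.06), Tg-ACE replicate 2 (0.06) or Tg-ACE replicate 3 (0.07), and its median was 0.15 without Tg-ACE replicate 1.

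Markers of T and NK cells were lower as a group in Tg-ACE, with 15 of 15 below 0, Il7r turning sign with relative log expression or upper-quartile factors (0.00128 and 0.0154), and a median log2 fold change of -0.47 (camera adjusted p = 0.00157; adjusted p = 0.956 with an estimated correlation). Only 1 of them, the interleukin-7 receptor gene Il7r, reached 5 CPM, and it stood at 466.7 ± 64.8 CPM in Tg-ACE and 468.2 ± 82.8 in WT (SD, n = 3). The list's median was -0.18 within Exp-156 and -0.69 within Exp-156b. Its call ended without WT replicate 1 (-0.03), Tg-ACE replicate 2 (-0.19) or Tg-ACE replicate 3 (-0.10), and the median was -0.85 without WT replicate 3 and -1.51 without Tg-ACE replicate 1. With a filter of 5 CPM in at least 3 samples 1 member was left, so the list could not be tested. MHC class II presentation genes had 12 of 13 members below 0 and a median of -0.27, and the list did not pass in the genotype fit (camera adjusted p = 0.384). It fell with the experiment code in the fit (median -0.31, camera adjusted p = 0.00307, or 0.806 with an estimated correlation). It also fell with the replicate block (-0.27, camera adjusted p = 3.6e-06, or 0.624 with an estimated correlation). Its members included the invariant chain Cd74 (841.3 ± 650.6 against 1160 ± 678.6 CPM, -0.46), the peptidase gene Ctse (-0.53), H2-DMb2 (-0.27) and the reductase gene Ifi30 (0.10). Without WT replicate 1 the values were 0.04 for Cd74, 0.22 for Ctse and 0.23 for H2-DMb2, and without Tg-ACE replicate 1 they were -1.30 for Cd74 and -0.03 for Ifi30, which was -0.03 also without WT replicate 3. The MHC class II median was -0.22 within Exp-156 and -0.12 within Exp-156b, and it was 0.36 without WT replicate 1, -0.60 without WT replicate 2, -0.54 without WT replicate 3, -1.05 without Tg-ACE replicate 1, -0.09 without Tg-ACE replicate 2 and 0.00 without Tg-ACE replicate 3.

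Altogether 6 of the 37 tested lists passed by camera with the preset correlation, 5 higher and 1 lower, and 0 passed with an estimated correlation or by fry, a rotation test of whether a list's genes move one way. Without WT replicate 1, 2 or 3 the number that passed was 18, 15 and 15. With the experiment code as a term 7 passed, MHC class II being added. In edgeR's quasi-likelihood test 0 members of any list passed over all genes and 0 adjusted over the list alone, and 1 member each of the alternative activation, interferon and phagocytosis lists had an unadjusted p under 0.05. DESeq2 and limma-voom on genotype alone called no list member over all genes. With the experiment code in the edgeR fit 0 passed over all genes, and DESeq2 with the code called Lgmn, Pf4, Folr2 and Plin2. In edgeR with the code, adjusted over the list alone, Slc25a20 passed in fatty acid oxidation and Plin2 and Slc25a20 in PPAR targets. Ccr1 and Pf4 passed there among chemokine genes, Folr2 among monocyte markers, Alox15 among eosinophil markers, Pf4 and Gp1ba among platelet markers, and Xist among sex-linked genes. Alox15 is also in the large peritoneal macrophage list, where it did not pass.

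**Figure D3:**
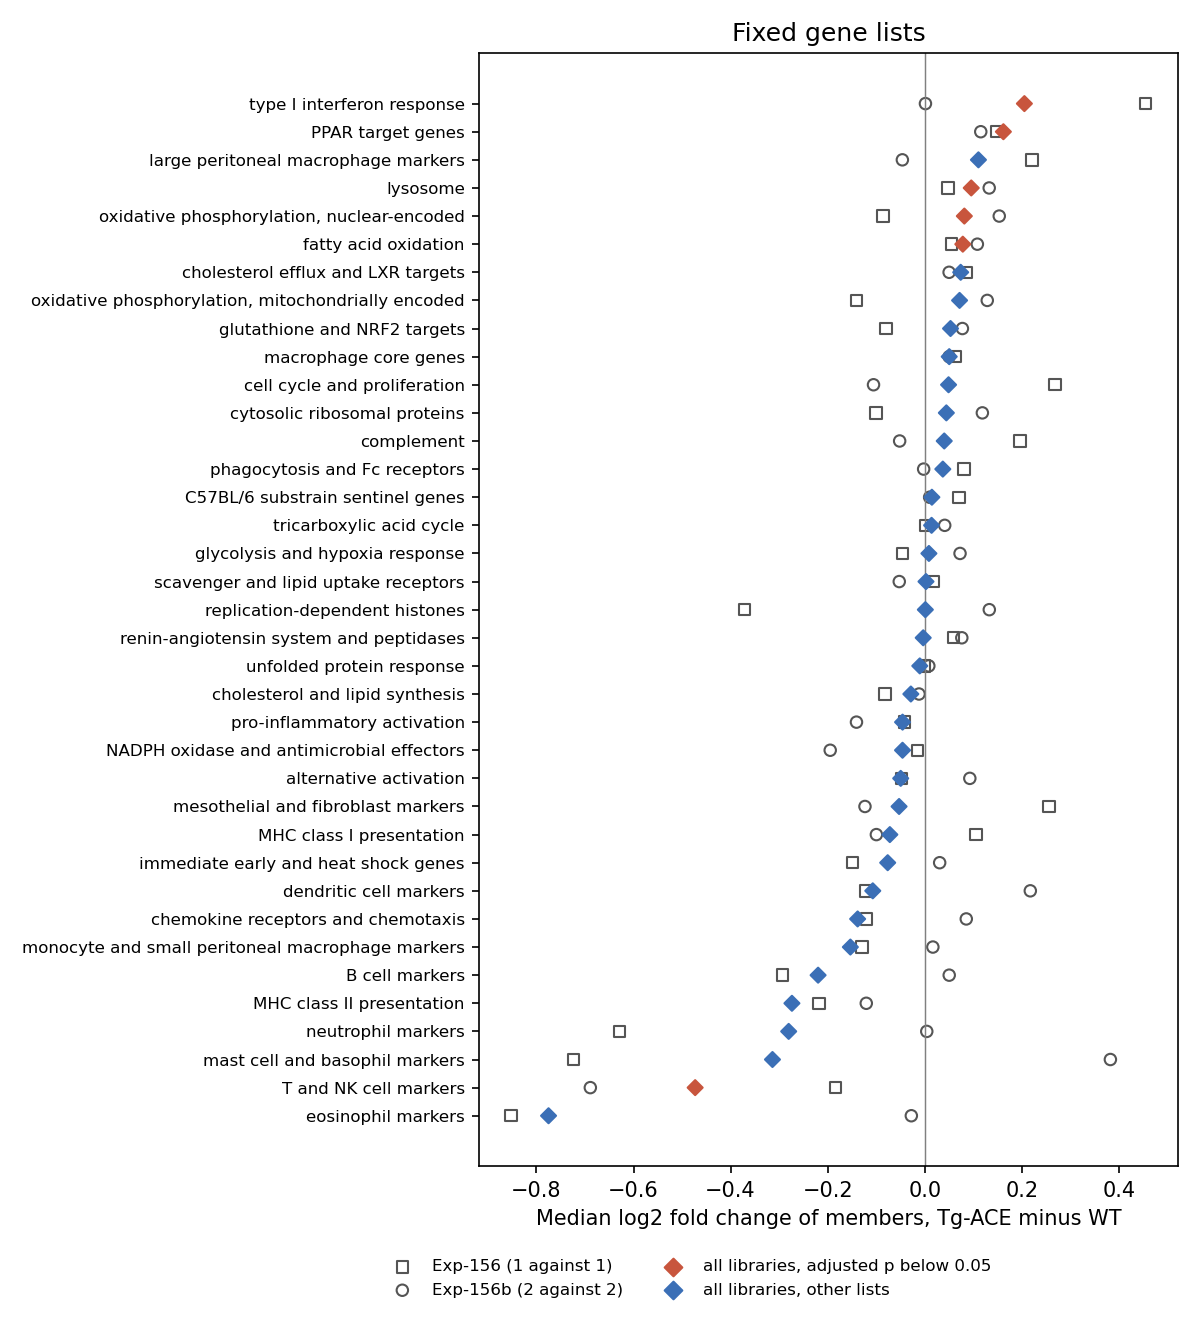
Median log2 fold change (Tg-ACE minus WT) of the tested members of each of the 37 lists, as filled diamonds for all 6 libraries and open symbols within Exp-156 (squares) and Exp-156b (circles). The 6 lists past camera's preset test are in red, from type I interferon response at 0.21 to T and NK cell markers at -0.47.

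Over all 6 libraries and without the block, the remaining 30 lists did not pass, with camera adjusted p from 0.168 upward. Among metabolic lists the median log2 fold changes were 0.07 for mitochondrially encoded oxidative phosphorylation (adjusted p = 0.592), 0.01 for the tricarboxylic acid cycle (0.359), -0.03 for cholesterol and lipid synthesis (0.468), 0.07 for cholesterol efflux and LXR targets (0.4545), 0.00 for scavenger and lipid uptake receptors (0.592), 0.01 for glycolysis and hypoxia response (0.862) and 0.05 for glutathione and NRF2 targets (0.468). Apoe, a cholesterol carrier in the efflux list, stood at 6303 ± 519.6 CPM in Tg-ACE and 5580 ± 466.6 in WT. Among macrophage function lists the medians were -0.05 for NADPH oxidase and antimicrobial effectors (adjusted p = 0.4545), -0.05 for pro-inflammatory activation (0.4545), -0.05 for alternative activation (0.834), -0.07 for MHC class I presentation (0.4545), 0.04 for phagocytosis and Fc receptors (0.229), 0.04 for complement (0.834), 0.00 for the renin-angiotensin system and peptidases (0.592), -0.14 for chemokine receptors and chemotaxis (0.922) and -0.01 for the unfolded protein response (0.834). Irg1, which makes itaconate in activated macrophages, stood at 6.75 ± 2.5 against 12.4 ± 9.31 CPM and the inhibitor of NF-kB Nfkbia at 45.4 ± 12.9 against 54.1 ± 16.6 CPM. In the alternative activation list Chil3 stood at 67.1 ± 50.3 against 42.2 ± 18.8 CPM and Tgfb1 at 237.7 ± 18.3 against 221.0 ± 13.4 CPM. The log2 fold change of Irg1 went from -0.87 to -0.05 without WT replicate 2, that of Nfkbia from -0.25 to 0.02 without WT replicate 1 and that of Chil3 from 0.67 to -0.09 without Tg-ACE replicate 2. The bridging molecules for dying cells Gas6 and Mfge8 stood at 45.7 ± 0.473 against 35.8 ± 5.96 CPM and 4003 ± 2567 against 2204 ± 1112 CPM. Thop1, an oligopeptidase, stood at 16.4 ± 2.47 against 12.9 ± 1.42 CPM (all SD, n = 3).

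Lists of RNA quality and growth had medians of -0.08 for immediate early and heat shock genes (camera adjusted p = 0.792), 0.04 for cytosolic ribosomal proteins (0.168), 0.00 for replication-dependent histones (0.834) and 0.05 for the cell cycle (0.4545). The 6 genes known to differ between C57BL/6 substrains had 0.01 (camera adjusted p = 0.468), with 3 above 0 and 3 below. A test for 1 shared direction cannot show whether the substrain backgrounds were alike. Cell type lists had medians of 0.11 for large peritoneal macrophages (camera adjusted p = 0.599), -0.15 for monocytes and small peritoneal macrophages (0.720), 0.05 for macrophage core genes (0.4545), -0.28 for neutrophils (0.592), -0.78 for eosinophils (0.4545), -0.31 for mast cells and basophils (0.592), -0.22 for B cells (0.4545), -0.11 for dendritic cells (0.592) and -0.05 for mesothelial cells and fibroblasts (0.599). With the replicate block the eosinophil list passed (median -0.43, camera adjusted p = 0.0147, or 0.827 with an estimated correlation). Its median was -0.85 within Exp-156, with 1 library per group, and -0.03 within Exp-156b. A filter of 5 CPM in at least 3 samples left 1 of its 5 tested members. The signalling adaptor Tyrobp among the core genes stood at 1222 ± 91.9 CPM in Tg-ACE and 1021 ± 109.4 in WT (SD, n = 3). Too few members were measured to test the erythroid and platelet list (4 members, median -0.39) and the sex-linked list (1 member, Xist, -0.43). The median, the mean and the camera direction differed in sign for the scavenger receptor, glycolysis, alternative activation, renin-angiotensin, chemokine, unfolded protein, immediate early, histone, monocyte, dendritic cell and mesothelial lists.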

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

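The difference between the Tg-ACE effect in Exp-156b and in Exp-156 was tested as an interaction in edgeR, and the use of camera's preset correlation to single out lists was chosen after it was seen that an estimated correlation gave none. No gene passed the interaction test in edgeR (981 at an unadjusted p under 0.05, smallest adjusted p = 0.646; no other tool was run for it). By camera with the preset correlation 11 of the 37 lists differed between the experiments, 0 with an estimated correlation (adjusted p from 0.745 to 0.943 for these lists), and Exp-156 has only 1 library per group, so the spread in these tests comes from Exp-156b alone and an equal spread in Exp-156 is assumed, not measured. Each value is the median over a list's members of the log2 fold change in Exp-156b minus that in Exp-156, and what singled it out is this difference between the experiments. Nuclear-encoded oxidative phosphorylation genes gave 0.245 (adjusted p = 1.5e-11 in camera), cytosolic ribosomal protein genes 0.24 (adjusted p = 9.2e-06) and glutathione and NRF2 target genes 0.23 (adjusted p = 5.2e-04). Type I interferon response genes gave -0.49 (adjusted p = 1.2e-07), cell cycle genes -0.35 (adjusted p = 5.2e-04), MHC class I presentation genes -0.26 (adjusted p = 0.0369) and T and NK cell markers -0.76 (adjusted p = 0.0451). Neutrophil markers gave 0.55 (adjusted p = 1.0e-05), mast cell and basophil markers 1.08 (adjusted p = 5.5e-05), replication-dependent histones 0.56 (adjusted p = 0.00951) and immediate early and heat shock genes 0.0869 (adjusted p = 0.0369). The 5 CPM filter left 4 of the 11 neutrophil markers, 3 of the 9 mast cell and basophil markers and 2 of the 5 histones. It left 1 of the 15 T and NK cell markers, so the values of these lists rest in large part on low counts. No biological explanation was tested, and experiment code and sex markers cannot be told apart here because both divide the libraries the same way.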

How the results depend on the processing

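The tests that combine the experiment code with another tool, with 1 library left out, with the length and GC offset or with an estimated correlation, the replicate block with an estimated correlation, the length and GC offset itself and the lists in Exp-156b alone were chosen after the result was seen. Against 0 genes in the genotype fit, DESeq2 called 9 (3 higher, 6 lower), limma-voom 1 lower, no filter 1 lower (of 17814 tested), the experiment code term 2 lower and Exp-156b alone 2 lower. With the replicate block 2 were called, both lower, and 8 lists passed, the MHC class II list and the eosinophil list (median -0.43, adjusted p = 0.0147 in camera) being added to the 6. Neither added list passed by camera in the block fit with an estimated correlation (adjusted p = 0.624 and 0.827). The block changed no other call. Leaving out 1 library gave from 0 to 1 genes, the 1 being Gm10709 without Tg-ACE replicate 3. Added settings called 37 (DESeq2 with the code, 19 higher and 18 lower), 2 (limma-voom with the code), 3 (robust edgeR with the code, Rpl29 being added), 1 (length and GC offset), 2 (offset with the code) and 2 (offset with the replicate block). The other scalings, robust edgeR and the 5 CPM filter (9709 genes) called 0. With the code in the fit, leaving out 1 library called 2 or 3 genes, and Gm10709 and Dhrs7 passed each time. The Ace log2 fold change stayed above 0 under all 17 alternatives, from 1.26 (without Tg-ACE replicate 1) to 2.46, with adjusted p from 0.136 to 1, and among the added settings it passed in DESeq2 with the code (adjusted p = 3.9e-05) and in edgeR with the code without WT replicate 3 (adjusted p = 0.0154). Lists past the threshold numbered 0 with an estimated correlation, 0 by fry, 0 with both an estimated correlation and the code, from 5 to 18 when 1 library was left out, and 5 with the 5 CPM filter, which left 1 T and NK cell marker and so no test of that list. Of 761 alternative values for 45 other named genes, 726 kept direction and side of the threshold, 18 passed and 17 changed sign. Those were Cd36 in Exp-156b alone (-0.00406), and Il7r with relative log expression (0.00128), upper-quartile factors (0.0154), DESeq2 (0.00125), limma-voom (0.00602), the replicate block (0.00133) and the code (0.000642), all within 1 SE of 0. With 1 library left out, ranges were -0.14 to 0.11 for Il7r, -0.81 to 0.22 for Ctse, -1.30 to 0.0424 for Cd74, -0.63 to 0.23 for H2-DMb2 and -0.51 to 0.0225 for Nfkbia (the sign of these last 4 changing without WT replicate 1), -0.0317 to 0.29 for Ifi30 (without WT replicate 3 or Tg-ACE replicate 1) and -0.0900 to 1.09 for Chil3 (without Tg-ACE replicate 2). Of 125 alternative values for 7 list medians, 88 were the same, 28 lost and 6 gained the call, and 3 changed sign, interferon without Tg-ACE replicate 1 (-0.0353, range to 0.30) and MHC class II without WT replicate 1 (0.36, range from -1.05) or Tg-ACE replicate 3 (0.00235). In Exp-156b alone the interferon list had a median of 0.01 and lost its call (adjusted p = 0.490 in camera). Library totals moved the median of all genes to -0.04, and the other scalings left it between -0.01 and 0.01. The cause of these shifts was not tested. Genes below about 0.12 CPM rest on fewer than 3 counts, so differences there were not detectable at this depth.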

Other observations

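The comparison of experiment codes and its gene choices, the test of the split count in the genotype fit, the test of chance placement of close genes, the tests of the chromosome 9 stretch, those of Rpl29 and Gm10709 and the offset fitted without a list's own genes were chosen after the result was seen. The Exp-156b libraries differed from the Exp-156 libraries far more than Tg-ACE did from WT. Expression was lower for monocyte, MHC class II, alternative activation and pro-inflammatory activation genes and for markers of several other cell types. In edgeR's quasi-likelihood test with genotype in the model, 5502 of 12827 genes (42.9%) changed between the 4 Exp-156b and the 2 Exp-156 libraries, 2559 higher and 2943 lower in Exp-156b and 1597 of them by more than 2-fold. Of 11 tested monocyte and small peritoneal macrophage markers 9 fell (median log2 fold change -2.52), including Ccr2, the receptor that brings monocytes into tissue, from a mean of 184.1 to 2.76 CPM. Of 13 MHC class II genes 12 fell (median -1.60), with H2-Eb1 from 596.8 to 128.9 CPM and Cd74 from 1713 to 644.2 CPM, while of 19 MHC class I presentation genes 9 rose and 1 fell (median 0.355), with H2-D1 from 3485 to 7111 CPM. In the alternative activation list 11 of 17 fell and 0 rose (median -1.17), with arginase 1, Arg1, from 931.5 to 23.7 CPM, Retnla from 218.7 to 12.6 CPM and the mannose receptor Mrc1 from 513.5 to 185.9 CPM. Pro-inflammatory activation genes also fell in 13 of 21 and rose in 2 (median -0.69). Complement genes fell in 10 of 17 and rose in 3 (median -0.95), and chemokine genes fell in 7 of 14 and rose in 0 (median -0.97). Eosinophil markers fell in 4 of 5 (median -2.87), with Alox15, a lipoxygenase, from 105.4 to 0.667 CPM. Alox15 is also a member of the large peritoneal macrophage list. Immediate early and heat shock genes fell in 14 of 22 (median -0.78), with Fos from 273.0 to 14.7 CPM and Klf2 from 203.9 to 9.27 CPM. Markers of mast cells and basophils fell in 8 of 9 (median -1.73), of T and NK cells in 11 of 15 (median -1.65), of neutrophils in 7 of 11 (median -1.39) and of dendritic cells in 6 of 10 (median -0.857), and the mix of cells and the state of the macrophages were not separated here. Against these, 2 immediate early and heat shock genes, 2 dendritic cell markers, 1 MHC class II gene and 1 monocyte marker rose. Among T and NK cell markers 1 rose, Il7r, from 383.5 to 509.4 CPM.

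Higher in Exp-156b were genes of antioxidant defence and sterol synthesis. Of 24 glutathione and NRF2 target genes 16 rose and 2 fell (median 0.41), with sulfiredoxin, Srxn1, from 70 to 224.4 CPM and the cystine transporter Slc7a11 from 6.57 to 15.5 CPM. Cholesterol and lipid synthesis genes rose in 13 of 27 and fell in 1 (median 0.43), with Sqle from 35.6 to 51.1 CPM. Nuclear-encoded oxidative phosphorylation genes rose in 26 of 62 and fell in 0 (median 0.21), while glycolysis and hypoxia genes rose in 3 and fell in 18 of 27 (median -0.41), with lactate dehydrogenase, Ldha, from 1026 to 583.0 CPM. The RNA quality list of cytosolic ribosomal proteins rose in 17 of 37 and fell in 0 (median 0.2487). Mitochondrially encoded oxidative phosphorylation genes rose in 6 of 13 and fell in 0 (median 0.7325). Among mesothelial and fibroblast markers 12 of 21 rose and 2 fell (median 1.0), with Col1a1 from 40 to 122.9 CPM. Large peritoneal macrophage markers fell in 12 of 19 and rose in 2 (median -1.22), with Adgre1 from 638.7 to 273.7 CPM and Timd4 from 7.13 to 0.252 CPM, while the transcription factor Gata6 rose from 6.05 to 16.2 CPM. Macrophage core genes fell in 10 of 19 and rose in 2 (median -0.42), with Csf1r from 761.4 to 567.7 CPM. Another member, lysozyme, Lyz2, stood at 15850 and 15440 CPM. By camera 25 of the 37 lists passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.130). The sex markers Xist and Ddx3y divide the libraries the same way, so sex, day and cell handling cannot be told apart as sources.

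The 6 samples make 10 splits into 3 against 3, too few for a share under 0.05. In the genotype fit the real split called 0 genes and the highest of the other splits 0, and all 10 splits give as many whenever the real count is 0, so this comparison decides nothing. The unadjusted count was 126 in the real split and from 51 to 153 in the other 5 splits with 1 Exp-156 library per side. The 153 came from the split that exchanges only the Exp-156 libraries and so keeps the genotypes apart within Exp-156b. The rest of these gave 51 to 59. The 4 splits with both Exp-156 libraries on 1 side had between 1727 and 2745 genes at an unadjusted p under 0.05, which points to the structure of the samples by experiment code. With the code in the fit the real split called 2 and the highest other 15, so that 2 of 10 gave as many. The unadjusted counts were 831 in the real split and 1129 in the split that exchanges only the Exp-156 libraries. They were at most 948 in the others, and 429 to 546 in the rest with 1 Exp-156 library per side. In both fits, exchanging the labels within Exp-156 gave more genes than the true labels. Counted over all genes, Exp-156 therefore did not bear out the genotype difference within Exp-156b. The split with 15 called genes joins both Exp-156 libraries with WT replicate 2, which points to WT replicate 2 standing apart within Exp-156b. For lists the real split passed 6, the fewest of all 10 splits, and the highest other 25, from the same split, so that 10 of 10 gave as many. The other splits with 1 Exp-156 library per side passed 7 to 13, and with the code in the fit the real split passed 7 and the others 9 to 20. Within Exp-156b alone 7 lists passed by camera with the preset correlation, and none with an estimated one (adjusted p from 0.8915 to 0.947 for these lists). The glutathione and NRF2 list and the ribosomal protein list were gained there, and the interferon list was lost.

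Among the 100 genes with the smallest p in the fit with the experiment code, 1 stretch of 5 Mb on chromosome 9 that begins at 106233455 held 11 (among them Alas1, Dusp7, Rpl29, Abhd14a, Abhd14b, Hyal1, Mst1r, Slc25a20, Nme6 and Ccrl2). Random sets of tested genes reached at most 8 in any 5 Mb (permutation p = 1e-04, the smallest that the permutations can give), which argues against chance placement there, although over the whole genome 25 had another within 2 Mb against a random mean of 24.4 (permutation p = 0.483) and 26 to 42 in the other splits with 1 Exp-156 library per side. Co-expression of neighbours stays open, since 1 other split had 13 in a stretch, on chromosome 17 and made up of MHC and complement genes, and another had 8 on the mitochondrial chromosome. A candidate explanation is a chromosome segment that differs by descent between the Tg-ACE and WT mice, and 100% of the 4 genes of this stretch chosen in Exp-156b alone (Alas1, Rpl29, Pcbp4 and Hyal1) kept their direction in Exp-156, but 4 genes are too few to decide (exact sign test p = 0.125). Of the 32 genes chosen in Exp-156b with a neighbour, 59.4% kept their direction, against 48.5% of the rest (Fisher's exact p = 0.392). The share fell short of the bound set beforehand for such segments as a general pattern. It cannot exclude a few segments, because random sets averaged 24.4 genes with a neighbour, so most of the 32 may be neighbours by chance. The largest stretch chosen in Exp-156b was 5 genes on chromosome 7, of which 3 kept direction.

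Gm10709 fell and Rpl29, 99.2% identical to it, stood higher in Tg-ACE, and 26 other transcripts match Gm10709 as closely as the search required, 3 of them in the table. Reads moving between copies could account for the lower Gm10709, since Rpl29 and those 3 copies together gained 94.7 CPM while Gm10709 lost 30.1 CPM. A shift among these 5 genes is argued against as the whole cause of the higher Rpl29, because their sum was 276.2 ± 28.6 CPM in Tg-ACE and 211.6 ± 2.03 in WT (SD, n = 3), a difference of 3.90 times its SE. The sum was higher in each Tg-ACE library (243.2, 291.8 and 293.7 CPM) than in any WT library (at most 213.0 CPM). No p-value was computed for it, and with 3 libraries per group the SE is itself uncertain. Reads from the 23 copies outside the table, not analysed here, stay open, and so does a sequence variant at either locus that differs between the mouse lines, as reads are not used here.

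The lists that passed the preset camera test were set against a trend with transcript length, as log2 fold changes went with length over genes (rho = -0.244, and 0.04 with a length and GC offset; genes are not independent replicates). With the offset the adjusted p was 0.0101 for fatty acid oxidation, 0.00735 for PPAR targets, 7.7e-05 for interferon response, 0.00735 for lysosome and 0.00152 for T and NK cell markers, and medians kept at least 83.3% of their size, which argues against the trend as their whole cause. For nuclear-encoded oxidative phosphorylation the adjusted p was 0.0139 and the median moved from 0.08 to 0.04, 45.9% of its size, and 46.15% with the offset fitted without the list's own genes. Short transcripts (median 1232 against 3377 bases over all genes) may therefore account for part of that list's shift, and the length trend and a change in these genes cannot be told apart because the list still passed while its median fell below the bound set beforehand. A biological effect of ACE on these lists stays open and did not pass with an estimated correlation.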
